A study of Mus musculus with 4 samples.

How the data were processed

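RNA sequencing measured gene expression in pancreatic islets of 2-week-old mice of the 129sv strain. There were 2 libraries from knockout mice (KO, labelled Ngn3Mettls KO) and 2 from wild-type mice (WT), and each library pooled more than 400 islets. Per the labels' protocols, ribosomal RNA was removed from total RNA, strand-specific libraries were made and 150-base paired ends were sequenced. Per the submitters' processing notes, the tools named were cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks and Cuffdiff, and the genome build was mm10. The gene annotation and the counting options are not given in the sources used here.

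The deposited table gave an estimated count and an FPKM (fragments scaled to transcript length and to the mapped fragments of the library) for each gene and library, per the file headers. It held 22564 rows of genes with 22481 symbols, and 1 empty line was not used here. The estimated counts the authors deposited are not raw. In each library, 92.8% to 93.5% of the values checked were whole multiples, within 0.1, of a step of 0.901 in KO replicate 1, 1.15 in KO replicate 2, 0.901 in WT replicate 1 and 1.09 in WT replicate 2. The values had therefore been scaled per library, and the others were fractional, so overlapping genes and close copies can share or exchange reads. The scaled totals were 4625920, 4686630, 4715154 and 4751087 in the same order. Divided by the step they were 5132727, 4057711, 5232232 and 4347126, which is the depth behind the values. The FPKM values deposited by the authors did not keep a fixed ratio to the counts for some genes. Counting noise and differences between islet pools set the precision, and the common biological coefficient of variation was 16.0%.

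The 79 symbols with more than 1 row were summed. The counts were rounded to whole numbers and filtered with filterByExpr, which left 12789 genes. They were normalised with TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM below means counts scaled to the usual fixed library total after TMM normalisation, and log2 fold changes are KO minus WT with the standard error from the same fit. The labels do not say whether the pools came from separate animals or litters, so the p-values of this gene test measure the spread between these pools.

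The choice of this test departs from the plan read literally. The plan, written before the data were examined, named limma on log2(FPKM + 1), with genes at a mean FPKM of at least 1, and edgeR only if the table held raw counts. The table held FPKM and scaled, estimated counts, which are not raw, so by its wording limma stayed the main test. edgeR was taken as the main test all the same, after the values had been looked at and before any test was run, because the clause on counts was read as covering estimated counts. It was also anticipated then that limma on FPKM would call fewer genes with 2 libraries per group. The result depends on that choice, since limma (limma 3.58.1) called 0 genes, and both results are given. Undoing the library scaling before edgeR was an alternative added after the data were seen.

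Gene lists were fixed in the same plan: 23 lists of islet cell types, other cell types of the pancreas, the m6A machinery and cell processes, of which 22 had at least 4 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. They were tested again with an estimated correlation and with fry, whose directional test is meant unless the mixed one is named. At the preset correlation camera's p-value rests on the spread across genes, taken as nearly independent, and does not measure the spread between pools. Genes named are Mettl3, Mettl14 and Neurog3. Ins1, Ins2, Gcg, Sst, Ppy, Mafa, Slc2a2, Ucn3, Pdx1, Nkx6-1 and Mki67 are always named. Added to these are up to 12 largest increases and 12 largest decreases of log2(FPKM + 1) among called genes without overlap between the groups, with a mean FPKM of at least 5 in the higher group and without predicted names. From each list come up to 4 called members or, with fewer than 2 such, its 2 members with the highest mean FPKM. Any other gene is named as chosen after its values were seen. Some genes that this rule or the lists name are not reported here.

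On simulated counts with the means and library sizes of the KO against WT comparison, over 12789 genes, edgeR recovered 17.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 95.5% of those changed 4-fold, with 7.30% of its calls false. The limma fit recovered 2.99%, 34.3% and 95.5%. Changed genes were drawn only above a minimum mean count. Every gene took the fitted trend of the dispersion, without a deviation of its own or a difference between replicate numbers. Recovery in the data may therefore be lower. In the same simulation camera called a changed list at the preset correlation but not at an estimated one (adjusted p = 0.470) or with fry (adjusted p = 0.293). Only 1 changed list was simulated, so this gives no rate of recovery. Since neither of those 2 tests called even that list, their failures below cannot decide whether a list changed. The estimated correlation was far above the preset for some lists. It was 0.67 for acinar, 0.71 for mesenchymal, 0.72 for proliferation and 0.96 for red blood cell genes. Preset p-values of such lists are too small, also with single libraries left out.

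Alternatives were DESeq2 1.42.0, other filters, scalings and pseudocounts, a replicate block, leaving out each library, and other list tests. Genomic positions are from the GENCODE M21 annotation of the same build, matched by gene identifier for 21818 of the rows. Figures and further tests used Python 3.11.15.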

Results

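The data describe the islet transcriptome of 2-week-old mice with a knockout that the labels name Ngn3Mettls, and of wild-type mice. The labels do not spell out which genes or exons were removed, and Mettl3, Mettl14 and Neurog3 were examined as the genes the name points to. Mettl3 and Mettl14 encode the core of the enzyme that writes N6-methyladenosine (m6A) on RNA, and Ngn3 (Neurog3) marks endocrine progenitors of the pancreas. The comparison, 2 KO against 2 WT pools of islets, asks which transcripts differ between the genotypes. Library totals were 5132727 and 4057711 estimated fragments in KO replicates 1 and 2, and 5232232 and 4347126 in WT replicates 1 and 2, after the authors' scaling was divided out. All values below are means ± SD over n = 2 libraries per group or single library values, and a number alone in parentheses after a gene is its log2 fold change, KO minus WT.

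Mettl3 and Mettl14 had lower mean values in KO and Neurog3 a higher one, and none of them passed the test. Mettl14 (chromosome 3, 123368297 to 123386108) measured 14.1 and 15.6 CPM in KO replicates 1 and 2 and 21.4 and 21.8 CPM in WT (log2 fold change -0.54 ± 0.22 SE, edgeR adjusted p = 0.369). Mettl3 (chromosome 14, 52294841 to 52305128) measured 18.6 and 17.2 CPM in KO and 29.3 and 17.1 CPM in WT (log2 fold change -0.38 ± 0.28 SE, edgeR adjusted p = 0.634), and its direction turned to 0.05 without WT replicate 1. Neurog3 was low in all 4 libraries, at 6.33 and 9.12 CPM in KO and 4.93 and 7.19 CPM in WT (log2 fold change 0.35 ± 0.40 SE, edgeR adjusted p = 0.768), with a log2 fold change of 0.061 without KO replicate 2 and 0.65 without WT replicate 2. Values summed over a gene do not check a deletion of single exons, and islets also hold cells outside the endocrine lineage, so these values do not settle the genotype of the libraries. The wider m6A machinery did not pass as a group: of 20 tested members 13 had a positive and 7 a negative log2 fold change, none was called, and camera gave an adjusted p of 0.353. Its members with the highest mean FPKM, Hnrnpa2b1 (-0.24) and Wtap (0.28), did not pass.

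The transcription factor genes Mafa and Nkx6-1 were among the genes lower in KO islets, and the hormone gene Ppy was among those higher in them. In all, 29 of 12789 genes passed the edgeR test, 17 higher and 12 lower in KO, and 0 genes passed limma on log2(FPKM + 1), the test the plan named first. Limma had 1367 genes at an unadjusted p under 0.05 and edgeR 1606, and the 29 genes had the same sign in both. The changes below are those of the edgeR test. The transcription factor Mafa (chromosome 15, 75745490 to 75748228), an activator of insulin transcription in mature beta cells, fell from 115 ± 7.10 CPM in WT to 9.99 ± 7.06 CPM in KO (log2 fold change -3.52 ± 0.36 SE, edgeR adjusted p = 0.0341). Arhgap36 (-3.48), Nnat (-2.81), the NMDA receptor subunit gene Grin1 (-2.10) and Gad1 (-1.62), which makes GABA from glutamate, also fell on the log2 scale. The size of the largest decreases depended on single libraries, with Mafa at -4.53 without KO replicate 1 and -2.94 without KO replicate 2, Arhgap36 at -4.20 without KO replicate 1 and -3.02 without KO replicate 2, and Nnat at -3.30 without WT replicate 1 and -2.10 without WT replicate 2. Smaller decreases were those of Papss2 (-1.27), Gng12 (-1.22), Ppp1r1a (-1.07), Itpkb (-1.05), Tmem206 (-1.04) and Nkx6-1 (-0.90), and Mtmr2 fell from 87.6 ± 1.48 to 43.9 ± 2.13 CPM.

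Among the genes that rose, Pigr (chromosome 1, 130826684 to 130852249), the receptor that carries polymeric immunoglobulins across epithelia, went from 3.08 ± 0.424 CPM in WT to 41.4 ± 10.2 CPM in KO (log2 fold change 3.73 ± 0.29 SE, edgeR adjusted p = 0.0103). The collagen gene Col20a1 rose by 2.25, Tmem255a by 1.56, Serpina10 by 1.55, Mrpl43 by 1.54 and the antimicrobial peptide gene Defb1 by 1.46. Ppy, the hormone of PP cells, rose from 362 ± 19.6 to 937 ± 193 CPM (1.37 ± 0.16 SE). The sodium channel gene Scn3a (1.29), the hyaluronan receptor gene Cd44 (1.16), the chaperone gene Pdia4 (1.07) and Ccnl2 (1.06) rose as well, and Car8 went from 49.8 ± 3.75 to 107 ± 14.4 CPM. The other 5 called genes, named here after their values were seen, were Lgals3bp (0.95), 8430408G22Rik (1.55), 2010107G23Rik (1.55), whose annotated span holds Neurog3, and Gm20605 and B130006D01Rik, which were near 0 in WT and overlap other genes on the same strand. Each called gene keeps its sign in all alternatives that tested it, and 6 are called without each single library: Col20a1, Gad1, Gm20605, Mafa, Pigr and Ppy. The number of calls depended on the libraries and the model, with 55 genes without KO replicate 1, 10 without KO replicate 2, 87 without WT replicate 1, 245 without WT replicate 2 and 150 with DESeq2.

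**Figure D1:**
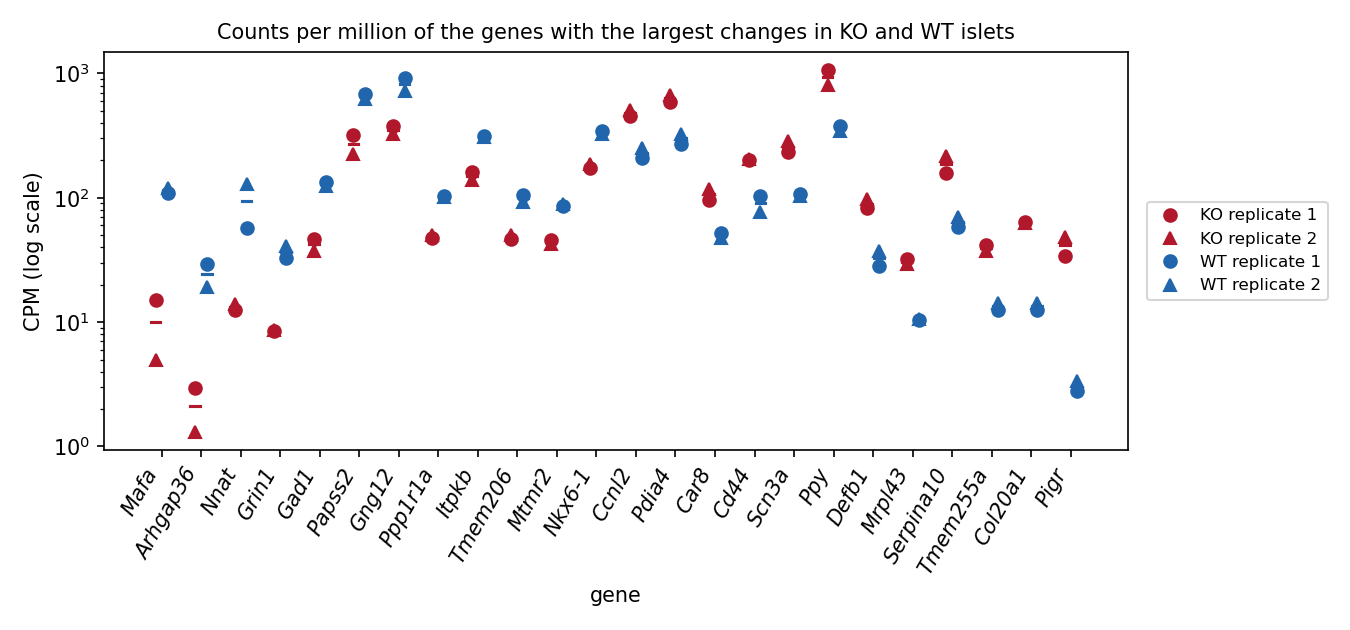
TMM-normalised CPM (log scale) of the named called genes with the largest changes, without predicted gene names and with a mean FPKM of at least 5 in the higher group, ordered by log2 fold change from Mafa at -3.52 to Pigr at 3.73. Each point is 1 library, red for KO and blue for WT, with circles for replicate 1 and triangles for replicate 2, and short lines are group means; the groups do not overlap for any gene shown, by the rule that chose them.

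As a group, the beta cell identity and maturation genes were lower in KO at camera's preset correlation (adjusted p = 1.79e-10). That p-value rests on the spread across genes and not on that between pools. The list did not pass with an estimated correlation (-0.013, adjusted p = 0.364) or with fry's directional test (adjusted p = 0.230). The simulated changed list did not pass those 2 tests either, so they cannot decide. Of 27 tested members 20 had a negative log2 fold change, and the median was -0.29. Over all genes tested, 4 were called lower (Mafa, Nnat, Papss2 and Nkx6-1), and adjusted over the list alone 10 were lower and 1, Iapp, higher. Nkx6-1, a transcription factor that keeps beta cells distinct from other endocrine cells, measured 180.5 ± 9.88 CPM in KO and 337 ± 14.0 CPM in WT. Past the threshold over the list alone and not over all genes, and chosen here after their values were seen, were Trpm5 (-2.22), Sytl4 (-1.21) and Ero1lb (-1.14), among others, and Ins2 and Slc2a2 passed there too. The glucose transporter gene Slc2a2 had a log2 fold change of -0.53 ± 0.16 SE (edgeR adjusted p = 0.259 over all genes), and passed without WT replicate 2 (adjusted p = 0.0351) and with DESeq2 (adjusted p = 0.0393). Leaving out single libraries moved it from -0.70 without KO replicate 1 to -0.36 without WT replicate 1, and the highest adjusted p was 0.867, without KO replicate 2. The insulin genes did not pass over all genes, at -0.58 ± 0.16 SE for Ins2 and -0.33 ± 0.19 SE for Ins1. Without WT replicate 2 the edgeR adjusted p was 0.000560 for Ins2 and 0.0105 for Ins1, and DESeq2 gave an adjusted p of 0.0101 for Ins2. Without WT replicate 1 the log2 fold changes were -0.33 for Ins2 (adjusted p = 0.222) and near 0 for Ins1 (-0.00251, adjusted p = 0.997), against -0.81 and -0.60 without WT replicate 2. Pdx1 (-0.22) and Ucn3 (-0.04) did not pass either, and Pdx1 ranged from -0.43 without KO replicate 1 to -0.054 without KO replicate 2. The call at the preset correlation was kept without each library.

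**Figure D2:**
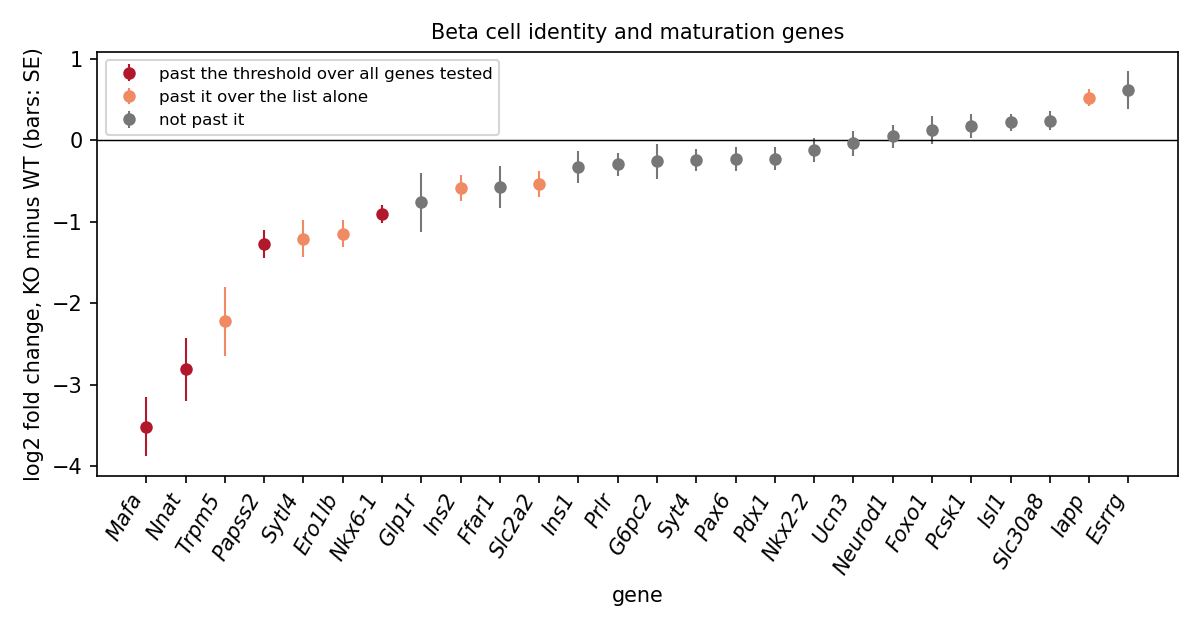
Log2 fold change, KO minus WT, of 26 of the 27 tested genes of the beta cell identity and maturation list, from Mafa at -3.52 to Esrrg at 0.62. Points are edgeR estimates from 2 KO and 2 WT libraries, bars are standard errors, and colours show whether a gene passed the adjusted threshold over all genes, over the list alone, or neither.

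Genes of delta, PP and epsilon cells were higher in KO as a group (camera adjusted p = 0.0140, adjusted p = 0.698 with an estimated correlation). Of 9 tested members 6 had a positive log2 fold change. Ppy was called over all genes, and Ppy and Ghrl, the ghrelin gene, chosen here after its values were seen (0.99), over the list alone. Sst (-0.38) and Pyy (0.26) did not pass, and Sst was at -0.59 without KO replicate 2 and -0.17 without WT replicate 1. The call of this list was lost without KO replicate 1 (adjusted p = 0.184) and with limma on log2(FPKM + 1) (adjusted p = 0.0615). Alpha cell genes did not pass as a group (camera adjusted p = 0.699, 12 tested), and Gc, chosen here after its values were seen (-0.80), passed over the list alone. Gcg, the gene with the most counts in every library, measured 52368 ± 8555 CPM in KO and 41133 ± 1731 CPM in WT (0.35 ± 0.12 SE, edgeR adjusted p = 0.314). Its log2 fold change was 0.17 without KO replicate 2 and 0.49 without KO replicate 1, and Ttr was at 0.02. Genes of immature or dedifferentiated beta cells did not pass as a group (camera adjusted p = 0.763), where Rfx6 (0.49) did not pass and Dlk1, chosen after its values were seen (-2.19), passed over the list alone. The insulin secretion machinery did not pass either (camera adjusted p = 0.582), where Chga (-0.27) and Scg2 (0.25) did not pass, Sytl4 passed over the list alone, and the median was positive while the mean and the test were negative. Genes disallowed in beta cells gave a camera adjusted p of 0.912, with a positive median and a negative mean and test direction, and Igfbp4 (0.16) and Nfib (0.12) did not pass. That list was past the threshold, higher without WT replicate 1 (adjusted p = 0.00839) and lower without WT replicate 2 (adjusted p = 0.0289).

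Glycolysis genes and nuclear genes of oxidative phosphorylation were lower in KO as groups at the preset correlation. Neither list passed with an estimated correlation (-0.0093 and 0.11), where the simulated changed list did not pass either. For oxidative phosphorylation the estimate lies above the preset 0.01, so its preset p-value overstates the evidence. Of 19 tested glycolysis genes 16 had a negative log2 fold change (median -0.24, camera adjusted p = 0.00701, adjusted p = 0.698 with an estimated correlation). None was called singly, and Pkm, a pyruvate kinase gene, had a log2 fold change of -0.35 ± 0.11 SE. The list shares 2 members with the beta cell list. Of 41 nuclear genes of oxidative phosphorylation 28 had a negative value (median -0.16, camera adjusted p = 0.0286, adjusted p = 0.972 with an estimated correlation), with Atp5b at -0.18 and Cox6c at 0.01. Without KO replicate 1 or WT replicate 1 the adjusted p was 0.0504 or 0.0703 for glycolysis. For oxidative phosphorylation it was 0.131, 0.0553 and 0.146 without KO replicate 1, KO replicate 2 and WT replicate 1.

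The p53 targets and cell cycle inhibitors were also lower in KO as a group at the preset correlation (median -0.21, 14 of 19 negative, camera adjusted p = 0.0133). With an estimated correlation of 0.10 the adjusted p was 0.860. That estimate lies above the preset 0.01, so the preset p-value overstates the evidence for these genes. Their members with the highest mean FPKM, Cdkn1b (-0.22) and Mdm2 (0.15), did not pass, and Plk3, a stress-response kinase gene chosen here after its values were seen (-1.76), passed over the list alone. That list's adjusted p was 0.191 without KO replicate 1 and 0.124 without WT replicate 2. Cell proliferation genes did not pass (camera adjusted p = 0.358, 40 tested), with Mki67 at 0.41 ± 0.26 SE (0.051 without WT replicate 2 and 0.89 without WT replicate 1), Ccnd1 at 0.03 and Ccnd2 at -0.24. As a group they were past the threshold when single libraries were left out, higher without KO replicate 2 (adjusted p = 0.00150), higher without WT replicate 1 (adjusted p = 3.88e-07) and lower without WT replicate 2 (adjusted p = 0.0489). The ER stress list gave an adjusted p of 0.221. Within it Pdia4 was called higher, and adjusted over the list alone 3 genes were higher and 4 lower, while Hspa5 (0.12) and Hsp90b1 (-0.15) did not pass, and the group was past the threshold, lower without KO replicate 2 (adjusted p = 0.0410) and lower without WT replicate 1 (adjusted p = 0.0338). Interferon response genes gave 0.628, with Ddx58 at 0.36 and Ifih1 at -0.25.

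Markers of cells outside the endocrine lineage moved in different directions. Immune cell genes were higher in KO (14 of 15 positive, median 0.70, camera adjusted p = 0.00318, adjusted p = 0.865 with an estimated correlation), with C1qa at 0.73 ± 0.19 SE and Cd74 at 0.70 ± 0.31 SE. None was called over all genes, and C1qa and H2-Eb1, chosen here after its values were seen (1.26), passed over the list alone. Acinar genes were lower (25 of 27 negative, median -0.33, camera adjusted p = 0.0115, adjusted p = 0.972 with an estimated correlation). The estimated correlation was 0.67 for acinar and 0.31 for immune genes, far above the preset 0.01. The preset p-values and the numbers of members moving 1 way overstate the evidence for these 2 lists. Cela2a varied more within groups than between them, at 662 and 1485 CPM in KO and 1406 and 962 CPM in WT, and Ctrb1 was at -0.40. The acinar direction turned without KO replicate 1 (adjusted p = 0.295) and its call was lost without WT replicate 1 (adjusted p = 0.639). The immune call was lost without KO replicate 1 (adjusted p = 0.184) and without WT replicate 2 (adjusted p = 0.117). Ductal genes did not pass (adjusted p = 0.697; Krt7 0.01, Krt18 -0.27), and Cldn4, chosen after its values were seen (0.70), passed over the list alone. Endothelial genes did not pass either (adjusted p = 0.699; Plvap -0.01, Egfl7 0.30) but were past the threshold, higher without WT replicate 1 (adjusted p = 0.0120). Mesenchymal genes (0.697, with Col3a1 at -0.33 and Sparc at 0.01) changed direction with the library left out, being higher in KO without WT replicate 1 and lower without WT replicate 2. Such fits mix replicate number with genotype. Fn1 of this list, chosen after its values were seen, measured 123 and 36.7 CPM in KO replicates 1 and 2 and 102 and 24.7 CPM in WT. With a replicate block in edgeR the list had a camera adjusted p of 0.732. Schwann and neural genes (0.163, with Th at 0.91, past the threshold over the list alone, and Mbp at 0.13) and red blood cell genes (0.697, with Hbb-bs at -0.18 and Hba-a1 at -0.36) did not pass, and red blood cell genes were past the threshold when single libraries were left out, lower without KO replicate 1 (adjusted p = 0.0123), lower without WT replicate 1 (adjusted p = 0.00117) and higher without WT replicate 2 (adjusted p = 0.0489). The adipocyte list had 1 tested member, Fabp4, at 0.26.

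Libraries differed within groups as well as between them. Of the variance of log2(CPM + 1), the first principal component held 41.5% and the second 37.0%. The second separated replicates 1 (-14.7 in KO, -20.8 in WT) from replicates 2 (3.47 in KO, 32.0 in WT). Leaving out 1 library therefore mixes replicate number with genotype, and directions that turned there may follow the number. Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was 0.965 between the KO libraries and 0.955 between the WT libraries, and 0.945 to 0.958 between groups. The Y-linked gene Uty, chosen here after its values were seen, measured 111 and 58.4 CPM in KO replicates 1 and 2 and 117 and 44.8 CPM in WT replicates 1 and 2. Immediate early genes, which respond to handling, did not pass as a group (camera adjusted p = 0.888), with a negative mean and a positive median and test direction. Fos measured 103 and 35.6 CPM in KO and 88.5 and 17.8 CPM in WT, and Btg2 was at 0.24. The group was past the threshold, higher without KO replicate 2 (adjusted p = 0.0139) and higher without WT replicate 1 (adjusted p = 0.00219). Mitochondrially encoded genes did not pass (adjusted p = 0.896, 11 tested). Among them mt-Co3 measured 66.3 and 2222 CPM in KO replicates 1 and 2 and 42.4 and 4059 CPM in WT replicates 1 and 2, whereas mt-Co1 measured 6869 and 6404 and 5914 and 4079 CPM. Of the 50-base words of mt-Co3, 99.9% also occur in annotated nuclear transcripts. The mitochondrial list was past the threshold when single libraries were left out, lower without KO replicate 2 (adjusted p = 0.0139), lower without WT replicate 1 (adjusted p = 0.00188) and higher without WT replicate 2 (adjusted p = 2.80e-05).

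**Figure D3:**
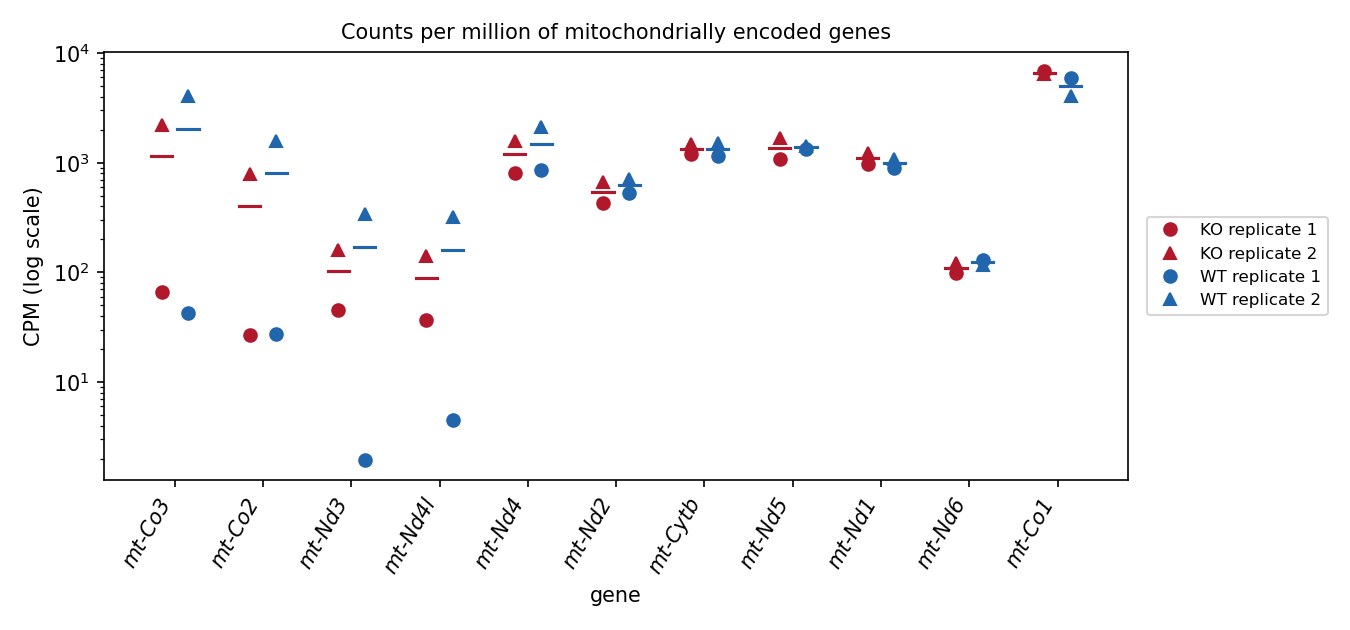
TMM-normalised CPM (log scale) of the 11 tested mitochondrially encoded genes, ordered by their ratio between libraries numbered 2 and 1. Each point is 1 library, red for KO and blue for WT, circles for replicate 1 and triangles for replicate 2, and short lines are group means; mt-Co3 spans 42.4 to 4059 CPM within WT alone.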

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

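Tests on data with the library scaling undone, with a robust quasi-likelihood fit and with a replicate block in limma were chosen after the data were seen; limma on log2(FPKM + 1) was the test the plan named first and became an alternative once edgeR was taken. The 29 calls (17 higher and 12 lower in KO) became 150 with DESeq2 (82 and 68), which shares all 29 and gave no adjusted p for 5393 genes. They became 66 (39 and 27) at an adjusted p under 0.1 and 60 (35 and 25) with the robust fit. With limma on log2(FPKM + 1) the count was 0 (0 and 0), and it stayed at 0 in all other limma fits without a block: pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, quantile, total without the top 50 genes, median ratio, no trend, and robust. These fits had 1152 to 1541 genes at an unadjusted p under 0.05. The cause of these differences was not tested. Leaving out 1 library, with the lone sample assumed to vary like the other group, gave 10 to 245 calls, 5 to 123 higher and 5 to 122 lower. The replicate numbers share no stated animal or litter; the fit with a replicate block called 214 genes (115 and 99), all 29 included and Slc2a2 added (adjusted p = 0.0286), limma with a replicate block called 55 (27 and 28), and the deviations of KO replicate 1 and WT replicate 1 from their group means correlated at r = 0.185. Undoing the scaling gave 30 calls. The number of lists past the threshold was 7. It was 6 with limma on log2(FPKM + 1), and 0 with an estimated correlation and with fry's directional test. It was 8 with fry's mixed test, which asks whether members change in either direction, and these were partly other lists. Of the 7, the beta, glycolysis, oxidative phosphorylation and p53 lists passed the mixed test. The immune (adjusted p = 0.191), acinar (0.859) and delta, PP and epsilon (0.0642) lists did not. The alpha cell (0.0339), ER stress (0.00895), interferon (0.00895) and Schwann and neural (0.00681) lists passed it, though not camera over all libraries. Over all alternatives the adjusted p of the 7 ran over 2.03e-18 to 0.364 (beta), 0.00151 to 0.698 (glycolysis), 5.94e-25 to 0.972 (acinar), 0.00915 to 0.860 (p53), 0.00380 to 0.972 (oxidative phosphorylation), 1.05e-07 to 0.865 (immune), 0.00150 to 0.698 (delta, PP and epsilon). Of 652 list alternatives 572 kept direction and side, 34 lost the call, 13 gained one and 33 turned direction. Of 767 alternatives for 35 named genes the numbers were 487, 270, 6 and 4. The list directions that turned when 1 library was left out follow, with the library and the range of the adjusted p over the 4 fits: proliferation without KO 1 or WT 2 (3.88e-07 to 0.678), immediate early without KO 1 or WT 2 (0.00219 to 0.203), immature beta without WT 1 (0.117 to 0.937), disallowed without KO 2 or WT 1 (0.00839 to 0.433), alpha without KO 2 (0.424 to 0.924), interferon without KO 2 (0.237 to 0.979), ductal without KO 2 or WT 2 (0.197 to 0.912), mesenchymal without KO 2 or WT 1 (1.37e-11 to 0.758), red blood cell without KO 2 or WT 2 (0.00117 to 0.178), mitochondrial without KO 1 or WT 2 (2.80e-05 to 0.184), acinar without KO 1 (5.94e-25 to 0.639), endothelial without KO 1 or WT 2 (0.0120 to 0.529). The disallowed list also turned with no count filter (0.991), fry (0.992), the replicate block (0.951), limma with a replicate block (0.905), limma without a filter (0.873) and limma at a mean FPKM of at least 5 (0.921, a value shared by the interferon, mitochondrial and ductal lists, which turned there too). The mitochondrial list turned with limma at pseudocounts of 1 (0.982), 0.1 (0.991) and 5 (0.997), and the insulin secretion list with quantile scaling (0.763). Mettl3 turned without WT replicate 1 (log2 fold change -0.713 to 0.0498 over the 4 fits). Ucn3 turned without KO replicate 1 and without WT replicate 1 (-0.227 to 0.174), and to 0.0574 with quantile scaling. The cause was not tested. Depth and 2 libraries per group limit what can be seen: edgeR recovered 17.9% of simulated 1.5-fold changes.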

Other observations

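The tests of beta cell share, of RNA from other cells, of overlapping genes and of mitochondrial content, and the choice to test pathways, came after the results they bear on were seen. Pathways named in the deposited annotation were tested with camera at the preset correlation, 276 of them with 10 to 300 tested genes. At an adjusted p under 0.05 there were 13, of which 2 were higher and 11 lower in KO. None passed with an estimated correlation (smallest adjusted p = 0.827), a test that the simulated changed list did not pass either. Proteasome genes were lower, with 37 of 42 negative (median -0.21, adjusted p = 0.00780), and so were genes of the citrate cycle, with 24 of 29 negative (median -0.23, adjusted p = 0.00903). The dopaminergic synapse set had 70 of 96 negative (adjusted p = 0.00304), and maturity onset diabetes of the young had 16 of 26 negative (adjusted p = 0.00780). Genes of the set named other glycan degradation were higher, with 15 of 16 positive (median 0.21, adjusted p = 0.0305). Larger annotated sets close to 3 of the fixed lists did not pass: glycolysis and gluconeogenesis (29 of 44 negative, adjusted p = 0.297), oxidative phosphorylation (67 of 103 negative, adjusted p = 0.223) and p53 signaling (24 of 58 negative, median 0.032, adjusted p = 0.968).

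Beta cell genes did not fall alike in KO. Had fewer beta cells been the whole cause, other genes of these cells would have fallen about as far as Nkx6-1 (-0.90), the least changed of the 4 called. The median of Ins1, Ins2, Iapp, Ucn3, G6pc2 and Slc30a8 was -0.15 (SD 0.40 over the 6 genes). None of these 6 was called over all genes, and they were chosen after the values were seen. The choice itself thus favoured a smaller fall, and Trpm5, Sytl4 and Ero1lb, also not called, fell further than Nkx6-1. The comparison cannot decide whether the share of beta cells was lower. Ucn3 (-0.04 ± 0.15 SE) and Mafa (-3.52 ± 0.36 SE) fell unequally, so 1 common loss does not account for every gene, although a smaller loss of cells stays open. More RNA from all kinds of non-endocrine cells alike would raise all their markers together, but over 7 such lists, 4 higher and 3 lower, the median was 0.0152 (SD 0.34). This does not bear on more RNA from a single kind of cell. Immune genes had a median of 0.70 and acinar genes of -0.33. A direct effect of the genotype on genes such as Mafa stays open as an untested hypothesis.

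Gm20605 and B130006D01Rik, chosen after their values were seen, were near 0 in WT and not in KO: Gm20605 (chromosome 5, 137629175 to 137642899) had 56.1 and 35.4 CPM in KO and 0 and 0.211 CPM in WT, and B130006D01Rik (chromosome 11, 95723587 to 95726710) had 16.2 and 20.4 and 0.642 and 0 CPM. Both overlap other genes on the same strand, so the estimation could have moved reads between them, in which case the others would fall. For Gm20605 the values argue against this. Lrch4 and Sap25 together held 7.83 CPM in WT against a gain of 45.7 CPM, so they could not have supplied it. The loss of their sum over the gain was -0.283 (SD 0.0378) and had no room to be large. Its negative sign means that their sum rose, with 22.3 and 19.3 CPM in KO and 6.98 and 8.68 CPM in WT. Lrch4 alone had 20.1 and 17.4 CPM in KO and 5.84 and 7.45 CPM in WT, and was not called (edgeR adjusted p = 0.122). For B130006D01Rik no loss was seen: Zfp652 and its neighbours summed to 425 and 433 CPM in KO and 375 and 367 CPM in WT (ratio -3.26, SD 0.315). It still stays open, because the common coefficient of variation amounts to 59.3 CPM at the WT mean of 371 CPM. A loss of 17.9 CPM could be hidden under such variation. Read-through transcription, an allele that differs between the mice and an effect of the genotype were not tested and stay open for both.

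Libraries numbered 1 and 2 differed in 43 genes in edgeR (16 higher and 27 lower in number 2), all but mt-Co2, mt-Co3 and mt-Nd4 nuclear, among them, named after their values were seen, Pnlip and Reg3b (higher in number 2) and Fn1, Csf1r and the Y-linked Uty and Ddx3y (lower). The tests here concern the mitochondrial transcripts alone: in KO replicate 1, KO replicate 2, WT replicate 1 and WT replicate 2, in this order, mt-Co2 had 26.6, 785, 27.6 and 1570.5 CPM. Less mitochondrial RNA in the libraries numbered 1 would lower all such genes. The 4 most different (mt-Co3, mt-Co2, mt-Nd3 and mt-Nd4l) had log2 ratios of number 2 over number 1 of 3.89 to 5.80. The other 7 genes had a median of 0.35, from -0.32 in mt-Co1 to 1.12 in mt-Nd4. The 4 were set apart by their ratio, so the gap itself is no evidence, but mt-Co1 was not lower in the libraries numbered 1. Reads that also match nuclear copies of the mitochondrial genome are a candidate explanation for which genes differ: the share of 50-base words found in nuclear transcripts rose with the ratio (Spearman's rho = 0.817, permutation p = 0.00337, 11 genes, which are not independent), from 99.9% in mt-Co3 to 0% in mt-Cytb, with mt-Co1 (51.1%) an exception. Why the libraries numbered 1 and 2 would differ in this, and any biological explanation, was not tested.

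A hypothesis written before its test was that transcripts with long 3' UTRs, where m6A is often placed, change in one direction in KO. Over 12556 genes with an annotated 3' UTR, Spearman's rho between its length and the log2 fold change was 0.0306. The difference between the WT libraries alone gave -0.0618 and that between the KO libraries -0.0490, so the relation was no larger than that within groups. Genes are not independent, and no p is given.

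The span of 2010107G23Rik (chromosome 10, 62107655 to 62143920), a called gene chosen after its values were seen, holds Neurog3, a gene the knockout's name points to. It had 45.2 and 50.8 CPM in KO and 17.3 and 15.4 CPM in WT (1.55 ± 0.17 SE, edgeR adjusted p = 0.0348). A candidate explanation, tested before the neighbours were seen, is extra copies of this region in the KO mice, as a transgene made from a large genomic segment could bring. The other 2 tested genes within 100 kb of Neurog3, Gm5424 (-0.08 ± 0.29 SE) and Tspan15 (0.18 ± 0.14 SE), had a median log2 fold change of 0.04995 (SD 0.18). Neurog3 itself was at 0.35 ± 0.40 SE. This argues against a gain over the whole interval as large as that of 2010107G23Rik. A smaller gain cannot be decided with these errors. A shorter segment stays open, and 1 of the 2 neighbours is a pseudogene in the annotation.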
